A study of Homo sapiens with 9 samples.

How the data were processed

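RNA was measured by sequencing in 9 libraries of IMR90 human embryonic lung fibroblasts, 3 of proliferating cells, 3 of oncogene-induced senescent cells with a scramble hairpin and 3 of senescent cells with ACSS2 knocked down. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a SMARTer mRNA kit. Groups and replicate numbers were taken from the sample titles and the genotype and treatment labels.

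The authors deposited 1 table of FPKM values, per the file headers, with 58735 gene rows and 1 column for each library. The aligner, counting tool, genome build, annotation and use of strand were not given in the sources used here. All 58735 gene identifiers matched the GENCODE 29 primary annotation, on GRCh38, which holds the same number of genes, so coordinates and merged exon lengths were taken from it. Symbols came from a gene name table for 58207 rows and from GENCODE for 528. Each FPKM value multiplied by its gene's merged exon length was a whole multiple of 1 step per library, within a tolerance of 0.01 reads, for 100% of values above 0. This gave whole reads per gene and totals of 16291707 to 19580329 reads per library. The divisor in the deposited FPKM values was 0.921 to 0.99 of the total of recovered reads, lowest in the senescent libraries. It kept a nearly fixed ratio to a median-of-ratios size factor, so the deposited values were already scaled between libraries. Counting error is covered by the reads, and values near 0 are limited by them. A floor of 3 reads over a group was used where a group had no reads, and it covers counting error only.

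Genes with an FPKM of at least 1 in at least 3 libraries were kept, 12717 in number, and 46018 were left out. Values were taken to log2(FPKM + 1), and fold changes are on that scale, which understates the change of low genes. Where a fold is given without a log2 scale, it is the ratio of mean FPKM. All 9 libraries entered one linear model per gene in limma 3.58.1 (R 4.3.3), with a variance prior that follows the mean. Tests took both directions, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each list was tested against the other genes with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the residuals. The fry test of limma was also run. It asks whether a list's genes move on balance one way and does not compare them with other genes.

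The design, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The 23 lists covered SASP cytokines and chemokines, SASP proteases, inhibitors and growth factors, de novo purine synthesis, purine salvage and degradation, one-carbon metabolism, pyrimidine and deoxynucleotide synthesis, cell cycle and DNA replication, CDK inhibitors and related genes, RAS and ERK output, NF-kB and C/EBP, interferon response and DNA sensing, lysosome, acetyl-CoA, fatty acid and sterol synthesis, glycolysis, stress and unfolded protein response, fibroblast matrix and contractile genes, mitochondrially encoded genes, ribosomal protein genes, clustered histones, and epithelial, endothelial, blood cell, and smooth muscle and pericyte markers. A list with fewer than 5 tested members had values and no test. Named genes were ACSS2, PAICS and HRAS, the 10 largest increases and the 10 largest decreases of the first 2 comparisons, and up to 3 members per list with the largest change. The largest changes had to pass the threshold, to have groups that do not overlap, a mean of at least 5 FPKM in the higher group and a proper gene symbol. Genes named outside this rule are marked in the text.

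The alternatives were other pseudocounts, filters and scalings, a replicate block, only the compared groups in the fit, other variance priors, a 2-fold threshold, protein-coding genes only, other list tests and leaving out each library in turn. 2 more were chosen after seeing the data: limma voom on the recovered reads, and removal of each library's trend on exon length and GC content. Overlap of calls between comparisons that share the senescent libraries was set beside 100 simulated data sets without differences. Replicate libraries were compared by a chi-square of their reads over genes with at least 20 reads in the pair, and no 2 libraries held identical values.

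The script was tested on simulated data, with reads drawn for the real genes from the means and totals of the real libraries. Their spread was taken from the fitted model, or preset for genes under the filter, and counting error was added on top. The fitted spread already holds counting error, so the simulated spread differs from that of the real libraries. In data made like the senescent against proliferating comparison, with 11929 genes tested, 77.6% of genes changed 1.5-fold, 92% changed 2-fold and 98% changed 4-fold were recovered, and 5 of 199 calls were false; of genes given the smallest simulated change, under 1.5-fold, 38% were recovered. In data made like the knockdown against senescent comparison, with 11985 genes tested, the shares were 72%, 90% and 100%, 30% at the smallest simulated change, and 8 of 198 calls were false. Lysosome genes were also lowered as a list in both, and count among the true calls. With 199 and 198 calls, against 9667 and 8557 in the real comparisons, these shares may not carry over to the real data. Tables were joined and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.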

Results

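RNA-seq was carried out on IMR90 cells, a line of human embryonic lung fibroblasts with a limited replicative lifespan that is widely used to study senescence, the lasting arrest of the cell cycle that follows stresses such as an activated oncogene. The 9 libraries formed 3 groups of 3: proliferating cells, cells in oncogene-induced senescence carrying a scramble control hairpin, and senescent cells in which ACSS2 was knocked down by a short hairpin RNA. ACSS2 is the nucleocytosolic enzyme that makes acetyl-CoA from acetate. The study asked how ACSS2 acts in senescent cells, and its title points to the senescence-associated secretory phenotype (SASP), the cytokines, proteases and growth factors that senescent cells release, and to purine synthesis through PAICS. Between 16291707 and 19580329 reads per library were recovered from the deposited FPKM values, and 11385 to 11639 genes reached 1 FPKM. Proliferating cells were labelled wild type, without a scramble hairpin, so the comparisons with them also differ in the vector. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

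The libraries separated by group. The first principal component of the 12717 tested genes held 69.5% of the variance and set proliferating apart from both senescent groups, and the second held 24.4% and set the knockdown apart from the scramble control. Replicate libraries differed by 2 to 3.52 chi-square units per degree of freedom, with the exception of knockdown replicate 2, which differed from knockdown replicates 1 and 3 by 6.2 and 6.57. Mitochondrially encoded genes took 2.5% ± 0.221 of recovered reads in proliferating, 3.91% ± 0.057 in senescent and 6.55% ± 0.229 in knockdown libraries (SD, n = 3 each).

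ACSS2 (ENSG00000131069, GRCh38 chromosome 20, 34872146 to 34927962) was read in every library first, as a check of the labels. Its levels were 17.1, 18.2 and 17.1 FPKM in the proliferating libraries, 4.96, 4.51 and 5.56 in the senescent libraries and 1.07, 0.832 and 0.885 in the knockdown libraries. It therefore fell 3.48-fold on entry into senescence (log2 fold change -1.62, SE 0.073, limma adjusted p = 2.83e-08) and a further 5.39-fold with the hairpin (-1.64, SE 0.073, adjusted p = 5.17e-08). PAICS (ENSG00000128050, chromosome 4, 56435741 to 56464579), a bifunctional enzyme of de novo purine synthesis, stood at 25.1 ± 0.77 FPKM in proliferating, 16.9 ± 0.662 in senescent and 11.4 ± 0.286 in knockdown cells (SD, n = 3 each), with log2 fold changes of -0.55 and -0.53 for the 2 steps (limma adjusted p = 1.16e-06 and 2.47e-06). The labels do not name the oncogene. HRAS (ENSG00000174775, chromosome 11, 532242 to 537287), the oncogene most used to induce senescence, was at 29.2 ± 1.5 FPKM in proliferating and 734.9 ± 46.5 in senescent cells, 25.2-fold higher, and reached 1133 ± 46.1 in knockdown cells (log2 fold change 0.62 against senescent, SE 0.0563, limma adjusted p = 7.01e-06).

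**Figure D1:**
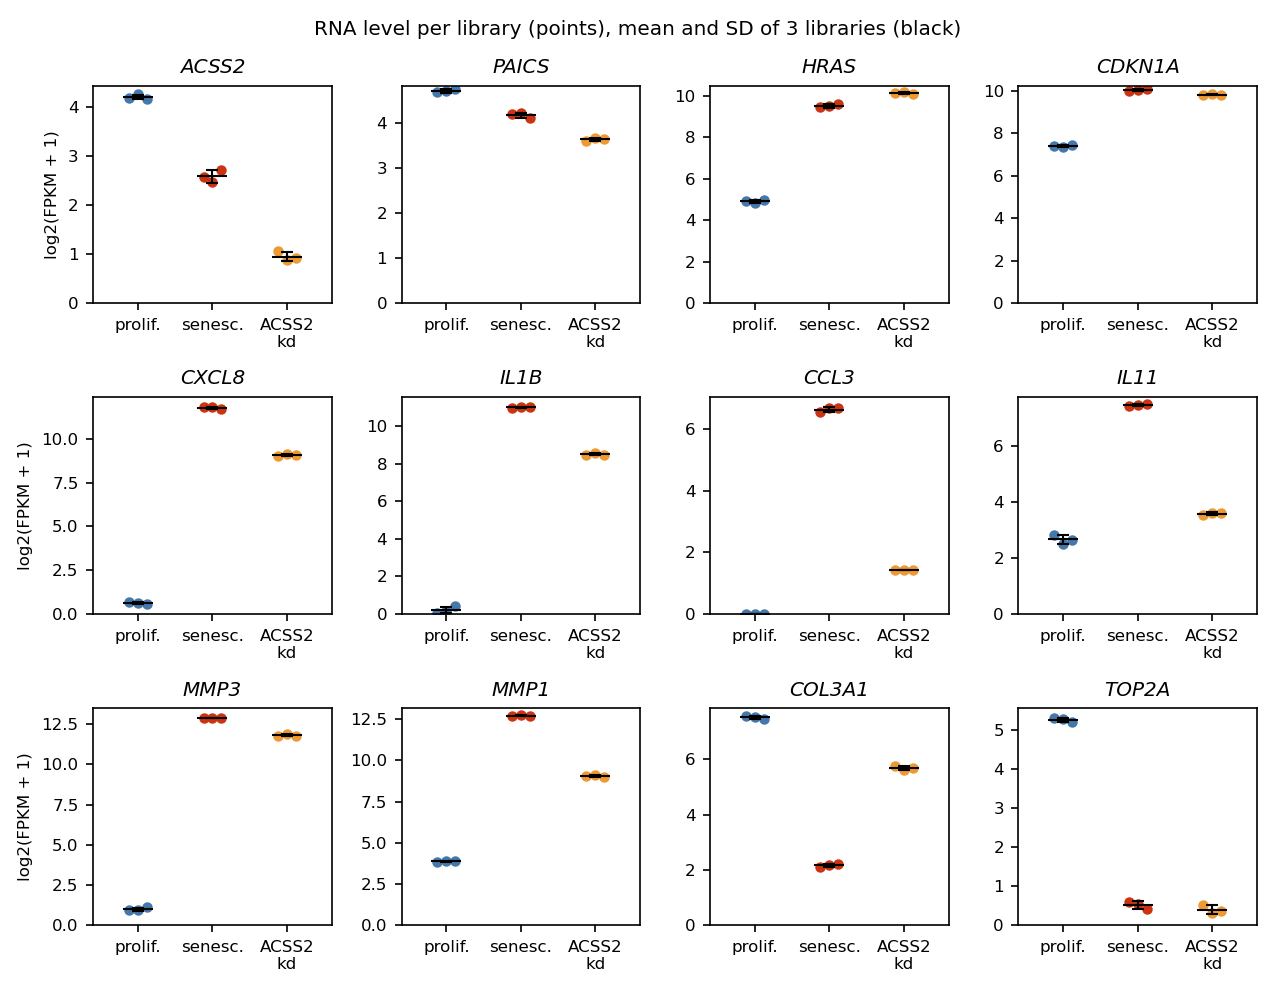
RNA level of 12 genes as log2(FPKM + 1) on the vertical axis, with 1 point per library for proliferating, senescent and ACSS2 knockdown senescent cells, and the mean and SD of 3 libraries in black. ACSS2 fell at both steps, the secreted factors CXCL8, IL1B, CCL3, IL11, MMP3 and MMP1 rose in senescence and were lower with the knockdown, and TOP2A stayed below 1 FPKM in both senescent groups.

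Senescent cells carried a secretory and inflammatory RNA profile, and most cell cycle transcripts were lower. The matrix metalloproteinase MMP3 rose from 0.975 ± 0.147 to 7618 ± 75.3 FPKM, the neutrophil chemokine CXCL8 from 0.539 ± 0.0494 to 3501 ± 143, and the inflammatory cytokine IL1B from 0.162 ± 0.145 to 2053 ± 11.8 (SD, n = 3 each). The interstitial collagenase MMP1 rose 498-fold to 6750 ± 118 FPKM. Among genes that fell, the mitotic topoisomerase TOP2A went from 37.7 ± 1.37 to 0.431 ± 0.0984 FPKM and the collagen gene COL3A1 from 182.8 ± 7.62 to 3.47 ± 0.164. These changes exceeded the spread between replicates, with limma adjusted p between 5.1e-15 and 2.13e-11.

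Of the 23 tested SASP cytokines and chemokines, 21 rose and 2 fell (median log2 fold change 5.14, or 6.36 with the 5 members that had no reads in proliferating cells set to a floor of 3 reads over the group). The camera test gave an adjusted p of 1.81e-10. CXCL5 and CXCL1, chemokines of the same receptor family as CXCL8, reached 562.9 ± 32.4 and 635.9 ± 6.96 FPKM, and TNFSF15, a member of the TNF family, reached 236.3 ± 3.42 (SD, n = 3 each). The 2 members that fell were CSF1 and CXCL12, at log2 fold changes of -2.57 and -1.37, named here after their values were seen. Among SASP proteases, inhibitors and growth factors, 30 of 43 rose and 13 fell (median 1.40, camera adjusted p = 2.02e-05). SERPINB2, a plasminogen activator inhibitor, rose 2035-fold to 639.9 ± 6.96 FPKM. Regulators and targets of NF-kB and C/EBP also rose, 22 of 28 against 5 that fell (camera adjusted p = 1.46e-05). Among them were PTGS2, the inducible cyclooxygenase, from 0.385 ± 0.0561 to 42.2 ± 1.85 FPKM, and TNFAIP3, a feedback inhibitor of NF-kB, from 1.85 ± 0.26 to 71.9 ± 1.66. BCL2A1, an anti-apoptotic target of NF-kB, had no reads in proliferating libraries and was at least 559-fold higher in senescent cells, against a floor of 3 reads over the group. By the same floor, PI3, an elastase inhibitor of epithelia, and LCE1F, a late cornified envelope gene of skin, were at least 4107-fold and at least 2201-fold higher, at 409.2 ± 11.2 and 354.3 ± 15.1 FPKM (SD, n = 3 each).

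Cell cycle and DNA replication genes fell in 60 of 62 cases and rose in 1 (median log2 fold change -2.35, camera adjusted p = 3.28e-20). CDC20, an activator of the anaphase-promoting complex, went from 37.1 ± 0.962 to 0.613 ± 0.0928 FPKM, and KIF20A, a mitotic kinesin, from 21.6 ± 0.848 to 0.123 ± 0.0424. Cyclin E gene CCNE1 was the member that rose, by 1.45 on the log2 scale, named here after its value was seen. CDK inhibitors and related genes rose in 23 of 33 cases and fell in 7 (camera adjusted p = 0.00816, adjusted p = 0.0503 with an estimated correlation). CDKN1A, the gene for p21, rose 6.31-fold to 1060 ± 28.3 FPKM, whereas CDKN2C fell by 2.98 on the log2 scale. Output genes of the RAS and ERK pathway rose in 22 of 29 cases and fell in 6 (camera adjusted p = 2.02e-05, adjusted p = 0.0847 with an estimated correlation), with the ERK phosphatase DUSP6 at 11.5 ± 0.987 and 102.4 ± 1.14 FPKM in proliferating and senescent cells. IER3 and SPHK1 rose 13.2-fold and 9.16-fold.

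Genes of acetyl-CoA, fatty acid and sterol synthesis fell in 34 of 38 cases and rose in 3 (median log2 fold change -1.06, camera adjusted p = 1.38e-09). The stearoyl-CoA desaturase SCD went from 588.5 ± 4.59 to 72.2 ± 0.429 FPKM, and ACAT2 and FADS2 fell by 3.10 and 2.70 on the log2 scale. Interferon response and cytosolic DNA sensing genes were lower in 29 of 36 cases and higher in 6 (median -1.16, camera adjusted p = 2.02e-05). IFITM3, a restriction factor against virus entry, went from 182.6 ± 3.16 to 23.3 ± 2.28 FPKM, and IFITM1 and GBP1 fell by 2.98 and 2.33 on the log2 scale. Fibroblast matrix and contractile genes fell in 33 of 45 cases and rose in 8 (camera adjusted p = 9.08e-07, adjusted p = 0.0847 with an estimated correlation), COL5A2 from 106.8 ± 3.66 to 6.96 ± 0.245 FPKM and FBLN1 from 30.3 ± 0.882 to 1.35 ± 0.114. Serine and folate one-carbon genes fell in 14 of 20 cases and rose in 5 (camera adjusted p = 0.0389, adjusted p = 0.213 with an estimated correlation and 0.0731 with libraries scaled to the same sum). PHGDH and PSAT1, which act in serine synthesis, fell by 2.90 and 2.39 on the log2 scale, as did ALDH1L2 by 2.27.

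De novo purine synthesis genes went both ways, 5 higher and 6 lower of 12, and the list did not pass its test (camera adjusted p = 0.328). PRPS2, IMPDH2 and PRPS1 fell by 1.43, 1.15 and 0.99 on the log2 scale. Purine salvage and degradation genes, 11 higher and 5 lower of 19, did not pass either (camera adjusted p = 0.071), although AMPD3, an AMP deaminase, rose from 5.06 ± 0.106 to 110.4 ± 1.31 FPKM, PNP 8.56-fold and NT5E 3.91-fold. Pyrimidine and deoxynucleotide genes, 6 higher and 11 lower of 22 (camera adjusted p = 0.159), included falls of 5.27 in TK1 and 3.26 in RRM2 and a rise of 3.15 in UPP1, all on the log2 scale. Glycolysis genes, 12 higher and 8 lower of 25 (camera adjusted p = 0.384), included rises in ENO2 and HK2 of 5.25-fold and 4.51-fold and a fall in PDK2 of 1.27 on the log2 scale. Genes of the integrated stress and unfolded protein response, 12 higher and 18 lower of 36 (camera adjusted p = 0.328), included a fall of 3.63 in NUPR1 and of 2.01 in SLC38A2 and a rise of 2.17 in ATF3. Lysosome genes rose in 28 of 45 cases and fell in 14 (camera adjusted p = 0.0153, adjusted p = 0.227 with an estimated correlation). CTSS, a cathepsin typical of antigen-presenting cells, went from 0.226 ± 0.0689 to 62.2 ± 2.5 FPKM, CTSK rose 4.41-fold and CTSC fell by 1.95 on the log2 scale.

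Mitochondrially encoded genes were higher in 12 of 13 cases (median log2 fold change 0.64, camera adjusted p = 7.46e-04, adjusted p = 0.339 with an estimated correlation), a direction that turned under quantile normalization (median -0.044). MT-ND1, MT-ND5 and MT-ND4L rose 3.55-fold, 2.2-fold and 1.97-fold in the values as deposited, MT-ND5 losing its call under quantile normalization, and the share of mitochondrial reads rose with the group as given above. Ribosomal protein genes fell in 39 of 47 cases and rose in 2 (camera adjusted p = 7.2e-06, adjusted p = 0.472 with an estimated correlation), among them RPS6 and RPL15 by 1.08 and 0.95 on the log2 scale. Clustered histone genes rose in 7 of 10 cases and fell in 2 (camera adjusted p = 0.0188, adjusted p = 0.0921 with an estimated correlation and 0.25 with no filter on low values), with H2BC8, H4C8 and H2BC4 at 12.6-fold, 7.06-fold and 5.71-fold. Reads can be shared between a histone or ribosomal protein gene and near-identical copies of it, so the values of single members are uncertain. Among markers of other cell types, endothelial markers rose in 5 of 6 cases (camera adjusted p = 0.046, adjusted p = 0.136 with an estimated correlation), a call lost in 8 of the 23 alternative settings that tested the list (adjusted p = 0.0506 under quantile normalization, for example), TIE1 to 6.27 ± 0.175 FPKM and ESAM to 2.71 ± 0.272, while TEK fell from 16.3 ± 0.507 to 1.37 ± 0.173. Smooth muscle and pericyte markers went 3 up and 2 down of 5 (camera adjusted p = 0.846, median 0.23, mean -0.28), with LMOD1 lower by 2.53 and CSPG4 and MCAM higher by 0.90 and 0.46 on the log2 scale. The tested epithelial marker CLDN4 rose 2.05-fold to 2.5 ± 0.264 FPKM, and the tested blood cell markers LAPTM5 and FCER1G rose to 5.29 ± 0.161 and 1.8 ± 0.386.

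Other large decreases were seen in the transcription cofactor LBH, 67.6-fold from 143.8 ± 3.77 FPKM, the heparin-binding growth factor PTN, 194-fold from 51.1 ± 1.7, the ubiquitin-conjugating enzyme UBE2C, 150-fold, the cyclic GMP phosphodiesterase PDE5A, 32.6-fold, and in KRT19, RGCC and RARRES2, by 4.61, 4.57 and 4.56 on the log2 scale. In all, 9667 of 12717 tested genes changed (limma, adjusted p under 0.05), 4789 higher and 4878 lower, of which 1083 and 1275 changed at least 2-fold. The 3 libraries of one group lay wholly above those of the other for 78.9% of genes, where chance gives 10%. With each library scaled to the same sum the median of all genes was -0.25 on the log2 scale, against 0.002 as deposited, and then 32.5% of changed genes were higher, against 49.5% in the values as deposited.

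**Figure D2:**
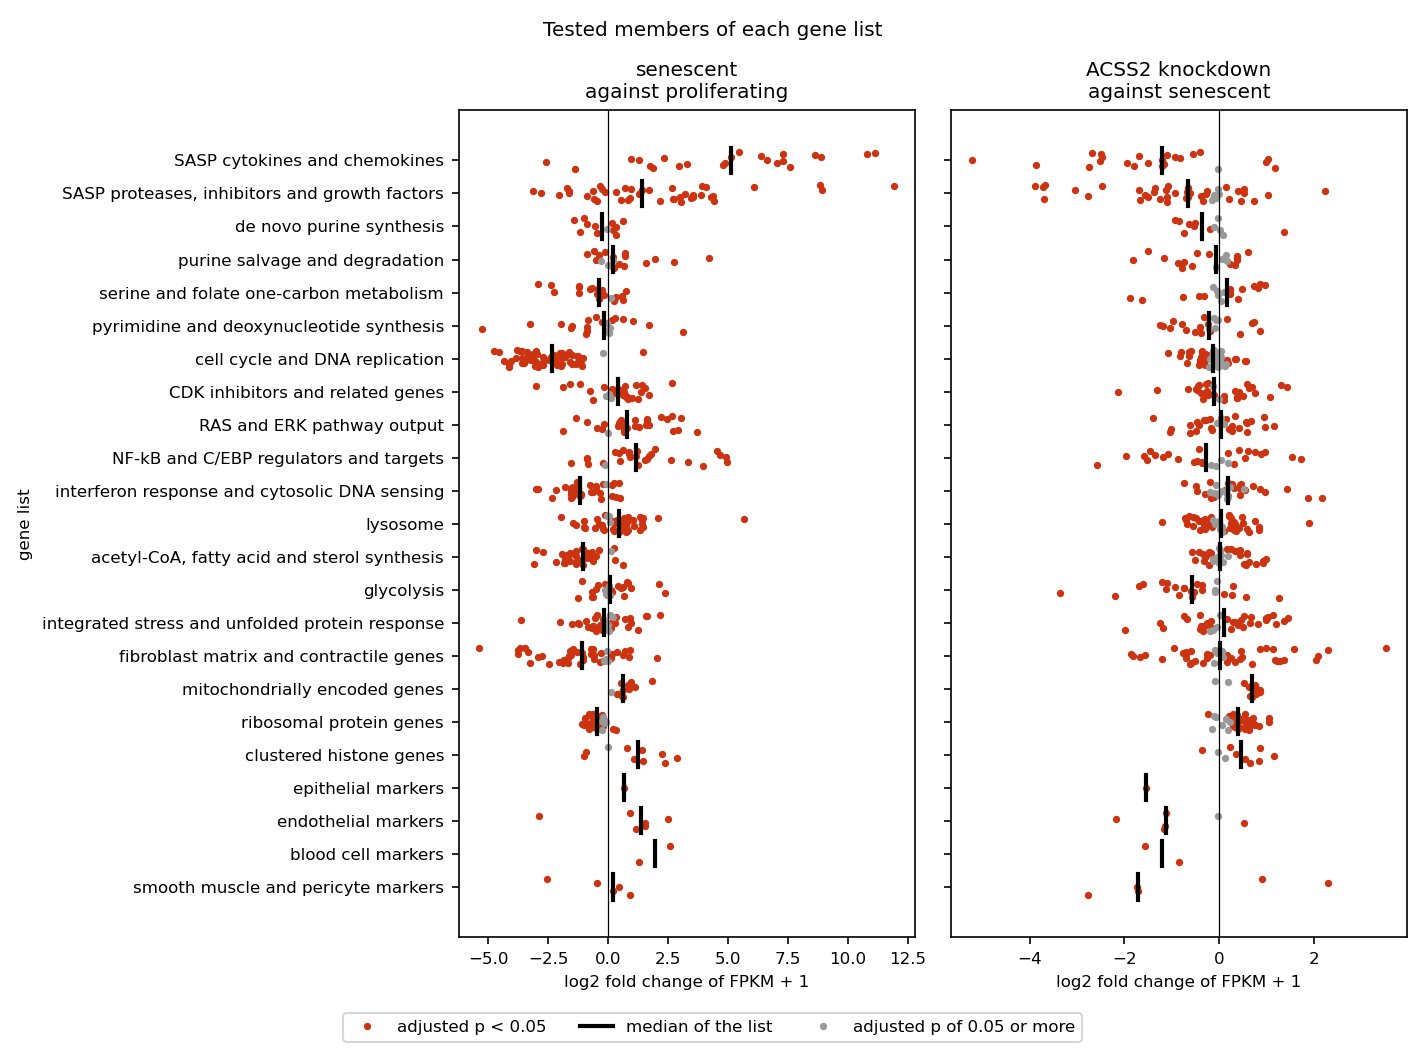
Log2 fold change of FPKM + 1 on the horizontal axis for each tested member of the 23 gene lists, senescent against proliferating on the left and ACSS2 knockdown against senescent on the right, with red points for limma adjusted p under 0.05, grey points for the others and a black bar for the list median. The median of the SASP cytokines and chemokines was 5.14 on the left and -1.21 on the right, and that of the cell cycle genes -2.35 and -0.12.

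The main comparison asked which genes differed in senescent cells with ACSS2 knocked down, against the scramble control. Secreted factors of the SASP fell: the chemokine CCL3 went from 99.1 ± 5.2 to 1.69 ± 0.00909 FPKM, the cytokine IL11 from 173.0 ± 5.03 to 10.9 ± 0.361, the gelatinase MMP9 from 14.4 ± 0.81 to 0.0338 ± 0.0381, and MMP10, a stromelysin, from 72.8 ± 1.56 to 4.58 ± 0.363 (SD, n = 3 each). Abundant factors of senescent cells fell as well, MMP3 from 7618 ± 75.3 to 3623 ± 155 FPKM, CXCL8 from 3501 ± 143 to 543.5 ± 23.9 FPKM, IL1B from 2053 ± 11.8 to 362.2 ± 13.2 and MMP1 from 6750 ± 118 to 527.3 ± 19.5. Collagen COL3A1 rose 14.5-fold to 50.5 ± 2.06 FPKM. The mitotic gene TOP2A was at 0.431 ± 0.0984 FPKM in senescent and 0.314 ± 0.108 in knockdown cells (limma adjusted p = 0.172).

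Of the 23 SASP cytokines and chemokines, 19 fell with the knockdown and 3 rose (median log2 fold change -1.21, camera adjusted p = 2.65e-06, adjusted p = 0.0607 with an estimated correlation). TNFSF15 fell 6.86-fold to 34.4 ± 1.75 FPKM. IL6 and IL1A, named after their values were seen, fell by 0.41 and 0.55 on the log2 scale, less than CXCL8 and IL1B, at -2.69 and -2.50. The 3 members that rose were CCL2, CSF1 and CXCL10, at log2 fold changes of 1.04, 0.98 and 1.19, also named after their values were seen. Among SASP proteases, inhibitors and growth factors, 29 of 43 fell and 9 rose (median -0.66, camera adjusted p = 1.05e-05, adjusted p = 0.0902 with an estimated correlation). TNFRSF1B, a TNF receptor that can be shed, fell 19.1-fold to 1.95 ± 0.0186 FPKM. MMP3 fell by 1.07 on the log2 scale. CCL3 and CCL3L3, which fell 58.7-fold and 60.3-fold, are near-identical copies between which reads can be split, so their separate values are uncertain.

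Glycolysis genes fell in 17 of 25 cases and rose in 5 (median log2 fold change -0.58, camera adjusted p = 1.99e-04, adjusted p = 0.238 with an estimated correlation). ENO2, an enolase, went from 211.6 ± 3.02 to 19.9 ± 0.871 FPKM, the lactate transporter SLC16A1 from 25.1 ± 1.01 to 4.66 ± 0.146, and the phosphofructokinase PFKP from 98.6 ± 3.56 to 29.9 ± 1.06 (SD, n = 3 each). De novo purine synthesis genes fell in 7 of 12 cases, PAICS among them, and 1 rose (median -0.36). The list did not pass its test (camera adjusted p = 0.102). It passed with no filter on low values (median -0.52, camera adjusted p = 0.0046). That setting adds genes under the filter to the list and to the genes it is compared with. IMPDH2, which commits purines to guanine nucleotides, was the gene that rose, from 21.4 ± 0.0433 to 57.2 ± 4.05 FPKM. PPAT, which catalyses the committed step of the pathway, went from 7.15 ± 0.175 to 3.57 ± 0.579 FPKM, and PRPS2 fell by 0.94 on the log2 scale. Purine salvage and degradation genes, 6 higher and 9 lower of 19 (camera adjusted p = 0.471), included falls of 1.81 in NT5C3A, 1.51 in HPRT1 and 1.16 in AMPD3 on the log2 scale. One-carbon genes, 10 higher and 5 lower of 20 (camera adjusted p = 0.471), included falls of 1.87 in GGH and 1.64 in MTFMT and a rise of 0.97 in PSAT1. Pyrimidine and deoxynucleotide genes, 5 higher and 12 lower of 22 (camera adjusted p = 0.102), included falls of 1.24 in RRM2B, 1.19 in TYMS and 1.04 in DCTD.

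Cell cycle and DNA replication genes were lower in 23 of 62 cases and higher in 6, and 33 did not pass the test (median log2 fold change -0.12, camera adjusted p = 0.0818). The list passed its test in the lower direction with a pseudocount of 0.1 (median -0.39, adjusted p = 0.0379), with libraries scaled to the same sum (-0.24, adjusted p = 0.0435) and with no filter on low values (-0.12, adjusted p = 0.0078). The last setting also adds genes under the filter to those the list is compared with. CDC25A, MCM2 and CCNE1 fell by 1.07, 0.84 and 0.80 on the log2 scale. CDK inhibitors and related genes, 15 higher and 16 lower of 33, had a median of -0.12 and a mean of 0.019 (camera adjusted p = 0.946), with TNFRSF10B lower by 2.12 and MDM2 and CDKN2B higher by 1.42 and 1.31. RAS and ERK output genes, 13 higher and 13 lower of 29 (camera adjusted p = 0.887), included falls of 1.39 in DUSP6 and 1.03 in IER3 and a rise of 1.15 in EGR1. NF-kB and C/EBP genes, 10 higher and 14 lower of 28 (camera adjusted p = 0.284), included falls of 2.58 in PTGES and 1.96 in TNFAIP6 and a rise of 1.73 in CEBPD. Interferon response genes, 16 higher and 8 lower of 36 (camera adjusted p = 0.11), included GBP1, 7.33-fold higher at 9.14 ± 0.177 FPKM, GBP2 from 0.545 ± 0.0794 to 4.68 ± 0.558 and IFITM3 from 23.3 ± 2.28 to 64.6 ± 3.04.

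Matrix genes split, 20 higher and 18 lower of 45 (camera adjusted p = 0.651): COL5A2 rose 5.44-fold and SPARC, a collagen-binding glycoprotein, rose from 137.9 ± 3.34 to 585.6 ± 12.3 FPKM. Sterol and fatty acid genes, 15 higher and 10 lower of 38 (camera adjusted p = 0.284), included rises of 0.93 in SC5D and of 0.99 in TM7SF2. Lysosome genes, 20 higher and 18 lower of 45 (camera adjusted p = 0.764), included LIPA, the acid lipase, from 9.03 ± 0.335 to 36.5 ± 0.625 FPKM, and a rise of 0.84 in ATP6V1A. Stress response genes, 18 higher and 14 lower of 36 (camera adjusted p = 0.471), included a fall of 1.98 in EDEM1 and rises of 1.44 in CHAC1 and 1.37 in SLC7A11.

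Mitochondrially encoded genes rose in 11 of 13 cases and none fell (median log2 fold change 0.68, camera adjusted p = 0.00127, adjusted p = 0.476 with an estimated correlation). MT-CO1 went from 5929 ± 33.9 to 10790 ± 191 FPKM, with MT-CO2 and MT-ND6 higher by 0.86 and 0.80 on the log2 scale, alongside the higher mitochondrial share of reads in these libraries. Ribosomal protein genes rose in 39 of 47 cases and 1 fell (median 0.39, camera adjusted p = 2.65e-06, adjusted p = 0.554 with an estimated correlation), RPLP0, RPL15 and RPS12 by 1.05, 1.04 and 0.83. Without knockdown replicate 2, the library that stood apart, the medians of these 2 lists were 0.66 and 0.30. Clustered histone genes, 7 higher and 1 lower of 10 (camera adjusted p = 0.0682), included rises of 1.16 in H2BC5, 0.86 in H2AC6 and 0.83 in H2BC21. Of the endothelial markers 4 of 6 fell and 1 rose (camera adjusted p = 0.11), TIE1, ROBO4 and ESAM by 2.17, 1.17 and 1.14 on the log2 scale. Of the smooth muscle and pericyte markers 3 of 5 fell and 2 rose (camera adjusted p = 0.471), CSPG4 and MCAM lower by 2.77 and 1.74 and ACTG2 5.01-fold higher. CLDN4, LAPTM5 and FCER1G fell by 1.54, 1.56 and 0.84.

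The largest single decreases also included MEDAG, an adipogenesis gene, from 66.1 ± 1.4 to 0.87 ± 0.218 FPKM, the serpin SERPINA9, 84.7-fold, the bone morphogenetic protein BMP6, 51.2-fold to 0.413 ± 0.0319 FPKM, PI3, 16.7-fold, LCE1F, 18.5-fold, and LCE2C, LCE2D and LCE2B, 23.6-fold, 63.5-fold and 25.3-fold. The LCE2 genes are near-identical copies, so their separate values are uncertain. Large increases included the transcription factor EGR4, from 0.992 ± 0.185 to 12.4 ± 0.673 FPKM, the dynein light chain DYNLRB1, from 9.84 ± 0.428 to 58.2 ± 5.61, the phospholipid flippase ATP8B1, 11.8-fold, PSTPIP2, EVI5L and RHOJ, 9.04-fold, 7.27-fold and 9.62-fold, and RGCC, 8.84-fold. OSTN-AS1 and THBS1-IT1 rose by 3.52 and 2.59 on the log2 scale, but they lie antisense to or inside other genes and the strand used in counting is not given in the sources used here. In all, 8557 of 12717 tested genes changed (limma, adjusted p under 0.05), 4293 higher and 4264 lower. Of these, 412 rose and 800 fell at least 2-fold, and 30 rose and 114 fell at least 4-fold. The groups did not overlap for 70.4% of genes, where chance gives 10%.

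Many genes that changed with senescence changed in the opposite direction with the knockdown, and are called moved back here. This counts direction only, and a gene may pass its proliferating level. CSPG4, for example, stood at 23.7, 45.2 and 5.78 FPKM in proliferating, senescent and knockdown cells. How many genes ended closer to the proliferating level was not counted. Of the 4789 genes higher in senescence, 2371 (49.5%) fell with the knockdown and 1073 (22.4%) rose further. Of the 4878 genes lower in senescence, 2262 (46.4%) rose with the knockdown and 1146 (23.5%) fell further. CXCL8, IL1B, MMP1 and PI3 were among the first set, and COL3A1, GBP1 and LBH among the second. Independent lists of these sizes would give 1606 and 1647 genes moved back, and 1617 and 1636 moved further. The senescent libraries enter both comparisons with opposite sign. In 100 data sets simulated without any difference, at most 1 gene was called in either set. Almost no gene can pass the threshold in such data, so this count cannot show how many of the real calls come from the shared libraries. Across genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was -0.39, against -0.50 in the simulated data, where it comes from the shared libraries alone. The covariance was -0.24 against -0.0062 simulated, a difference of -0.24. The simulated covariance already holds what the fitted spread of the shared libraries gives. With 3 senescent libraries, these could not be split into parts of at least 2 to measure this directly. An error common to all 3 senescent libraries is not in the simulation, so part of the excess may come from such an error.

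**Figure D3:**
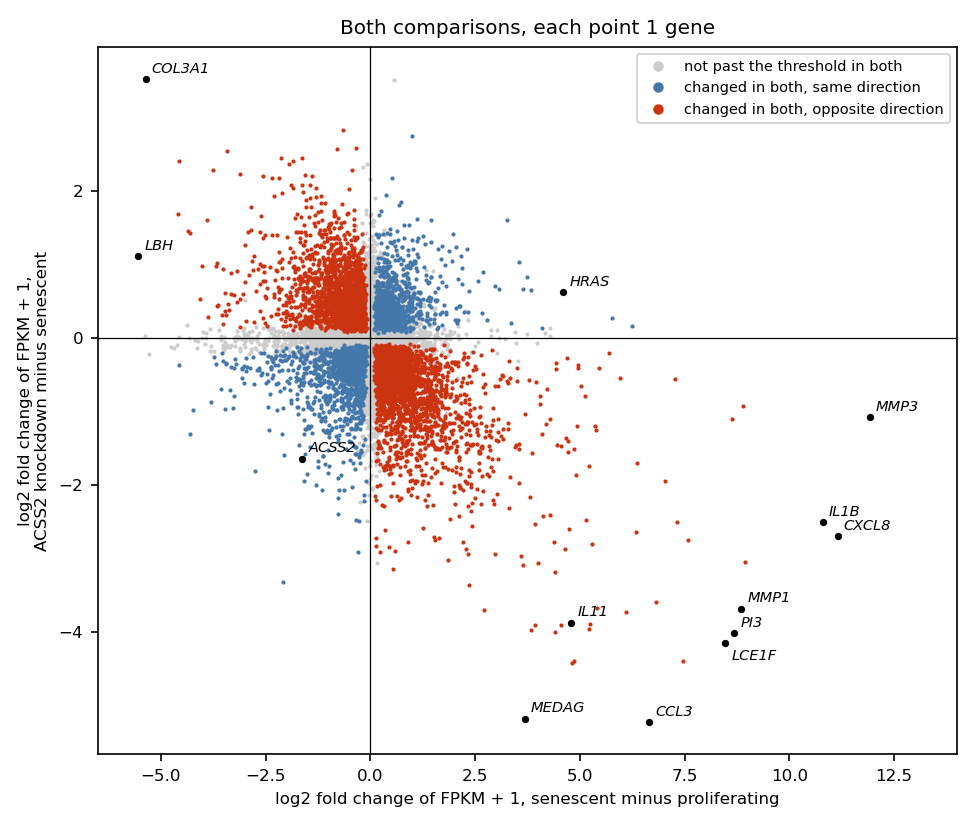
Log2 fold change of FPKM + 1 of each of the 12717 tested genes, senescent minus proliferating on the horizontal axis and ACSS2 knockdown minus senescent on the vertical axis, with genes changed in both comparisons in red where the directions are opposite and in blue where they are the same. Labelled genes are in black; the 2371 genes of the lower right part that changed in both comparisons include CXCL8, IL1B, MMP1 and CCL3, and the upper left part holds 2262.

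Compared with proliferating cells, knockdown cells remained senescent in RNA profile. Cell cycle genes were lower in 61 of 62 cases (median log2 fold change -2.60, camera adjusted p = 9.17e-21), and SASP cytokines and chemokines were still higher in 20 of 23 cases and lower in 2 (median 3.07, or 4.73 with the 5 members without proliferating reads at the floor, camera adjusted p = 3.05e-08). CXCL8 and MMP3 lay 8.47 and 10.84 above proliferating cells on the log2 scale, and CDKN1A 2.42, whereas MMP9 differed by 0.036 with a limma adjusted p of 0.619. SASP proteases, inhibitors and growth factors were higher in 25 of 43 cases and lower in 15 (camera adjusted p = 0.0293, adjusted p = 0.184 with an estimated correlation). Genes of acetyl-CoA, fatty acid and sterol synthesis were lower in 33 of 38 cases and higher in 4 (camera adjusted p = 5.84e-08), SCD by 3.00 on the log2 scale. De novo purine synthesis genes were lower in 8 of 12 cases and higher in 4 (camera adjusted p = 0.0939). Mitochondrially encoded genes were higher in 13 of 13 cases (camera adjusted p = 2.95e-05, adjusted p = 0.217 with an estimated correlation), beside their larger share of reads, and ribosomal protein genes in 11 of 47 with 15 lower (camera adjusted p = 0.739). Interferon response genes were lower in 24 of 36 cases and higher in 9 (camera adjusted p = 0.00574, adjusted p = 0.169 with an estimated correlation), and glycolysis genes lower in 17 of 25 and higher in 4 (camera adjusted p = 0.0021, adjusted p = 0.184 with an estimated correlation). In all 9710 genes differed (limma, adjusted p under 0.05), 4930 higher and 4780 lower, and 938 and 1463 of them at least 2-fold. With each library scaled to the same sum the median of all genes was -0.21 on the log2 scale, against 0.028 as deposited, and 34.6% of changed genes were higher, against 50.8% as deposited.

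Counts of called list members adjusted over the list alone were the same as those over all genes tested for the comparison of senescent with proliferating cells, except that 61 cell cycle genes, 8 CDK inhibitors and related genes and 41 ribosomal protein genes were then lower. For the knockdown against senescent cells the exceptions were 31 lower SASP proteases, inhibitors and growth factors, 7 higher purine salvage genes, 22 lower cell cycle genes and 11 higher NF-kB and C/EBP genes. With an estimated correlation, the list calls that held were those of both SASP lists, cell cycle, NF-kB and C/EBP, interferon and sterol genes for senescence, and none for the knockdown against senescent cells. In the comparison of knockdown with proliferating cells they were SASP cytokines, cell cycle and sterol genes.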

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

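Of 4925 values recomputed for 220 results under 26 alternative settings, not all of which apply to each result, 4838 kept their direction and their side of the threshold. The median of mitochondrially encoded genes in senescence turned to -0.044 under quantile normalization. The other 12 medians that changed sign belong to lists past the threshold in neither setting. In senescence these were glycolysis (-0.195 with the same sum, -0.053 under quantile normalization), purine salvage (-0.018 with the same sum) and smooth muscle markers (-0.041 with no filter). With the knockdown they were smooth muscle markers (0.11 with no filter), RAS and ERK output (-0.009 with no filter, -0.103 with a filter at 5 FPKM, -0.014 without knockdown replicate 1, and a range of -0.032 to 0.089 when leaving out each library in turn), stress response (-0.011 with a filter at 5 FPKM), CDK inhibitors and related genes (0.01 under quantile normalization) and lysosome (-0.003 with length and GC trends removed). The cause was not tested. 2 of the settings, voom on recovered reads and removal of length and GC trends, were chosen after seeing the data. A 2-fold threshold left 2358, 1212 and 2401 genes for senescent against proliferating, knockdown against senescent and knockdown against proliferating, by its own construction. A filter at 5 FPKM tests fewer genes and left 6344 in the first and 6461 in the third. For the knockdown against senescent cells, cell cycle genes passed the list test with a pseudocount of 0.1 (median log2 fold change -0.39), with no filter (-0.124), with libraries scaled to the same sum (-0.244) and with fry (-0.124), and purine synthesis genes passed with no filter (-0.516) and with fry (-0.358). Without a filter, genes at low values join those a list is compared with, so the passes in that setting may come from the changed background. Fry also called purine synthesis in senescence (-0.265). It called every tested list in senescence, and all but the one-carbon, RAS and ERK output and lysosome lists with the knockdown. A fry call therefore does not set the cell cycle or purine synthesis genes apart. With an estimated correlation, SASP cytokines (-1.214, adjusted p = 0.0607) and SASP proteases (-0.659, adjusted p = 0.0902) lost their call in the knockdown. Apart from the fry calls, which ask another question, the cause was otherwise not tested. Leaving out each library in turn gave 9203 to 9844, 8005 to 8459 and 9312 to 9713 changed genes for the 3 comparisons and 4274 to 4598 genes moved back, and ACSS2 in the knockdown stayed between -1.697 and -1.572. No pairing by replicate number was detected: same-numbered libraries had deviations correlated at -0.091 to 0.015, and differently numbered ones at -0.057 to 0.083. A pairing by culture or infection that left no shared variation would not be seen this way. With the replicate block 9496, 8314 and 9565 genes changed and 4463 moved back. The 46018 genes under the filter were not tested, and whether depth limits them was not measured.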

Other observations

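The cornified envelope and pericyte values, the mitochondrial comparisons and the tests on SASP genes below were chosen after the results were seen, and the mitochondrial explanation was reworded once its value was known. The splits of the samples were planned. A run of skin barrier genes on chromosome 1 changed in these fibroblasts. In the epidermal differentiation complex (GRCh38, 152084144 to 153310718), 16 of 61 annotated genes were tested. Late cornified envelope genes and involucrin (IVL), structural proteins of the outer skin, had no reads in proliferating cells for the genes named next and rose in senescence, LCE1F to 354.3 ± 15.1 FPKM, LCE2C to 176.3 ± 7.49, LCE3D to 80.2 ± 4.28, LCE7A to 37.1 ± 3.77 and IVL to 20.2 ± 2.39 (SD, n = 3 each). With the knockdown they fell to 19.1 ± 1.02, 7.48 ± 1.07, 12.2 ± 1.48, 1.58 ± 0.131 and 1.35 ± 0.13 FPKM. The small proline-rich genes SPRR2D and SPRR2E went the other way, from 1.74 ± 0.36 to 7.35 ± 0.922 and from 1.18 ± 0.0255 to 3.11 ± 0.0129 FPKM (limma adjusted p = 6.81e-07 and 4.98e-07). SPRR2A, of the same family, fell from 3.46 ± 0.32 to 1.85 ± 0.385 FPKM (limma adjusted p = 2.71e-04). Whether reads are shared between the SPRR2 genes was not tested.

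Markers listed for smooth muscle and pericytes also moved with the knockdown, the surface proteoglycan CSPG4 from 45.2 ± 2.21 to 5.78 ± 0.301 FPKM, the adhesion molecule MCAM from 34.8 ± 1.22 to 9.73 ± 0.55 and the contractile actin ACTG2 from 32.7 ± 0.347 to 164.1 ± 6.56 (SD, n = 3 each). The receptor gene NOTCH3, named after its values were seen, went from 5.67 ± 0.307 to 1.05 ± 0.0339 FPKM. PTPRC, a marker of white blood cells, had a highest group mean of 0.0181 FPKM, in senescent cells, and CD14, a monocyte marker, one of 0.623, in knockdown cells.

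Technical explanations were set against the fall of the cornified envelope genes. Reads split between copies keep their sum, but the summed CPM of the 23 LCE genes was 12.7-fold lower in knockdown than in senescent libraries, 27.6 to 32.9 against 366 to 386. Keratinocytes that carry KRT5 and KRT14 would bring these keratins into the senescent cultures, and the higher of them was at 0 FPKM. Keratinocytes without KRT5 and KRT14 would not be seen this way, so they stay open. Whether large falls cluster in the complex stays open: the odds ratio of a 4-fold fall inside against outside was 200, but these genes prompted the test, and 15 of the 16 had a proliferating mean under 1 FPKM and passed the filter through the senescent groups. An effect of the hairpin other than on ACSS2 stays open as well, since there was 1 knockdown group.

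For the fall of SASP genes, 3 technical explanations were set against an effect of the knockdown. A lower oncogene level was read from HRAS, since the labels do not name the oncogene. HRAS was 25.2-fold higher in senescent than in proliferating cells. It was higher still with the knockdown, by 0.62 on the log2 scale (SE 0.056), at 1084 to 1176 FPKM against 700 to 788. These values argue against a lower HRAS level, while a fall of another oncogene stays open. RAS and ERK output genes went both ways, 13 higher and 13 lower of 29 (median 0.03, camera adjusted p = 0.887). Knockdown and senescent libraries thus differ in HRAS RNA as well, and whether this bears on the SASP genes was not tested. Proliferating cells mixed into the knockdown cultures would move cell cycle genes back by the same share as SASP cytokines, and 60 cell cycle genes moved by a median of -1.04% of the way to the proliferating level (95% interval -2.37 to -0.52), against 74.6% for 21 SASP cytokines. A length or GC trend would leave the median near 0 once removed, and it was -1.277. The resampled SE was 0.333, taken from the values before the trends were removed. This SE and the 95% interval above resample genes, not libraries, so they do not measure the spread between samples. An effect of the hairpin on other targets stays open, and may act on the same genes.

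For the rise of mitochondrially encoded transcripts, a larger mitochondrial share of RNA with an unchanged profile would raise the 13 genes alike, but their log2 fold changes varied by 11.07 chi-square units per degree of freedom over 12 degrees, from -0.08 for MT-ND1 and 0.18 for MT-ND2 to 0.86 for MT-CO1 (SE 0.083, 0.088 and 0.066). The library that stood apart does not carry it, since the median without knockdown replicate 2 was 0.656. A larger share with a changed profile stays open, and mitochondrial ribosomal RNA took 0.55% ± 0.026 of reads in senescent and 0.797% ± 0.064 in knockdown libraries (SD, n = 3 each). RNA quality, which can act on transcripts unequally, was not measured and stays open beside an effect of the knockdown on mitochondrial transcripts.

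With 3 libraries against 3, the 10 splits of 6 libraries are too few for a share under 0.05, so they decide nothing. In each case only 1 split, the real one, gave as large a result. The real values and the highest of the other splits were 9667 and 0 genes for senescent against proliferating, 8557 and 0 for knockdown against senescent, 9710 and 1 for knockdown against proliferating, and 4633 and 0 genes moved back. The sizes of the list medians were 5.14 and 1.74 for SASP cytokines, 1.40 and 0.52 for SASP proteases and 2.35 and 0.83 for cell cycle genes in senescence, and 1.21 and 0.53 for SASP cytokines and 0.66 and 0.26 for SASP proteases with the knockdown.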
